A study of Homo sapiens with 12 samples.

How the data were processed

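Bulk RNA sequencing was analysed in 12 libraries of HL-60 cells, 3 each of vector control, JMJD3 overexpression, parental and JMJD3 knockout, grouped by their sample titles. Per the labels' protocols, RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit (catalogue number FC-122-1001), which does not mark strand. Reads from a gene and an overlapping or antisense gene therefore cannot be told apart. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.4, RSEM, edgeR and the GRCh38 build, and the series' design text also names BWA, an analysis of variance and Cufflinks. Which of these made which column is not given in the sources used here.

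The authors deposited a table per comparison, with a count column and an FPKM column per sample, and, per the file headers, a log2 fold change, a p-value and an adjusted p-value per gene. The deposited count columns are RSEM expected counts multiplied by a single factor per library, as read from the values: after division by the recovered factor, 92.9% to 94.0% of values up to 1000 were whole within 0.02. The factors lay between 0.772 and 1.197. In the knockout table they lay within 0.416% of the median-of-ratios factors of all 6 libraries. In the overexpression table they differed from these by up to 18.9%, and by up to 1.34% from factors computed with the third replicates apart. The values thus fit a separate scaling of the third replicates, which the sources used here do not state. The columns were divided by the recovered factors, and the resulting expected counts were rounded to whole numbers. The deposited FPKM values, per the file headers, were used only in an alternative. The authors' deposited log2 fold changes and adjusted p-values were used only for comparison: they correlated with the fold changes computed here at a Spearman coefficient of 0.968 and 0.933 across genes. The authors' deposited lists mark 1958 genes as significant on overexpression, with an absolute log2 fold change of 1 or more, and 1716 on knockout, with 0.59 or more and an adjusted p of up to 0.119, so the thresholds differed.

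The tables held 60660 and 60662 genes with values, and 13 lines of the overexpression table without values were left out. For overexpression, 28 symbols had been turned into dates by a spreadsheet and were restored from the Ensembl identifier. Positions and gene types come from GENCODE 29 (GRCh38), which held 57044 and 57046 of the identifiers. Some genes with near-identical copies are named as uncertain, but not every named gene was checked for such copies.

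Each comparison was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, default expression filter, robust quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Standard errors were derived from that fit, as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM values are TMM-scaled within a table. Levels are set across the tables as CPM by library total for the all-or-none genes, which were chosen on TMM-scaled CPM. They are set across as TMM-scaled CPM for CXCL8, CCL2, TRAF1, EGR1, FOS, CDKN1A, KDM6B, MYC, TYMS, CEBPB and INSIG1. The same holds for CBR1, ZNF37A, MSRB3, VIT, ZNF566 and FAM129B where their opposite changes are named. The separate tables limit both comparisons. In all, 28 gene lists with 718 entries were fixed before the data were examined, as were the tests of the comparisons in the report and the rule for named genes. Some alternatives, and some tests in the closing section, were chosen later and are named there. Lists with 5 or more measured members (26 per comparison) were tested on log2 CPM (prior count 2) with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry. Overlap of calls was tested with two-sided Fisher's exact tests. The named genes were KDM6B; the 8 largest rises and 8 largest falls among called genes whose libraries did not overlap and which reached 5 CPM in the higher group, leaving out symbols starting with LOC, LINC, RP11-, CTD-, AC0, AL, MIR or SNOR, antisense genes, pseudogenes and genes without a symbol; the 4 smallest p-values under the same exclusions; up to 4 members by p of each list with 2 or more calls; KDM6A, EZH2, CEBPB, CEBPA, CEBPE, SPI1, MYC, CDKN1A, ITGAM, CD14 and MPO; and of genes called in both comparisons the 6 opposite and 4 same-direction genes with the largest smaller change. CD14 did not pass the expression filter. Other list members named to complete a small count were chosen after their values were seen. Some genes that the rule takes are not reported here.

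Whether replicate numbers pair the samples was checked from the correlation, across genes, of deviations from the group means. In the overexpression comparison it was 0.199, 0.238 and 0.553 for the 3 same-numbered pairs, so the numbers may pair the samples, although replicates 1 and 2 correlated as well with each other's partner (0.255 and 0.203). The pairing thus rests mainly on the third replicates. In the knockout comparison the correlation was 0.036, -0.12 and -0.069. The main fit of each comparison, fixed beforehand, has no pairing term, so its p-values ignore what the third replicates share. Counts with the replicate number as a block are given beside it. The fit was tested on simulated counts. For overexpression (14056 genes) it recovered 4%, 34%, 82% and 98% of genes changed by 0.3, 0.5, 1 and 2 on the log2 scale and called 8 unchanged genes. For knockout (14024 genes) it recovered 50%, 62%, 96% and 94% and called 17 unchanged genes. Only 50 genes were changed at each size, and libraries were drawn independently. In the data 7207 and 5357 genes were called, so the adjusted threshold was less strict there, and these shares do not give the recovery in the data. At this depth, 3 counts over a group were taken as the floor for a count of 0. Alternatives were DESeq2 1.42.0, limma voom, other scalings and filters, a replicate block, leaving out each library, the authors' adjusted p, the deposited columns undivided, FPKM, a batch term, and replicates 1 and 2 alone or summed.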

Results

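Messenger RNA was profiled by bulk sequencing in HL-60, a human promyelocytic leukaemia cell line that can mature towards neutrophils or monocytes. The gene of interest was KDM6B, whose product JMJD3 removes methyl groups from lysine 27 of histone H3, a mark laid down by Polycomb enzymes. Cells transduced with a JMJD3 expression vector were set against cells transduced with a control vector, and JMJD3 knockout cells were set against parental cells, with 3 libraries in each of the 4 groups. The comparisons ask which transcripts follow a gain and a loss of JMJD3. In order of replicate number, the overexpression libraries held 28086883, 32080606 and 39031309 expected counts and the vector controls 26861291, 31472527 and 37941428. The knockout libraries held 29518543, 33772903 and 28563550 and the parental libraries 37065301, 34862590 and 43647710. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. In the overexpression comparison, replicates 1 and 2 lay close together (chi-square per gene of 1.96 in the vector control and 1.68 in the overexpressing cells, where 1 is counting noise). These values lie above counting noise, so the libraries were not merged, but repeat preparations of one culture would lie above it too. Whether replicates 1 and 2 are separate samples is therefore open, and counts with both summed into 1 library are given beside the others. Replicate 3 of each group lay far from both (33.5 to 44.7 per gene).

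KDM6B (ENSG00000132510, GRCh38 chromosome 17, 7839904 to 7854796, plus strand, protein coding) was 31.6 ± 5.95 CPM (counts scaled to library size) in the vector control and 93.8 ± 8.57 CPM in the JMJD3-transduced cells (mean ± SD, n = 3). Its log2 fold change was 1.57 ± 0.148 (SE), with an adjusted p of 0.000129. In the knockout comparison KDM6B was 57.4 ± 1.41 CPM in parental and 39.8 ± 4.70 CPM in knockout cells, a log2 fold change of -0.53 ± 0.070 with an adjusted p of 2.44e-05. KDM6B was at 37.2, 45.2 and 36.9 CPM in the knockout libraries and at 56.6, 56.6 and 59.0 CPM in the parental libraries, so every knockout library lay below every parental one. KDM6B transcript was thus still present in the cells labelled as knockout. RNA level does not report on the protein, and where the gene was edited is not given in the sources used here. On log2(FPKM + 1) values the KDM6B difference between knockout and parental cells was -0.45 with an adjusted p of 0.155 by limma, where the other settings gave adjusted p-values from 2.95e-17.

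**Figure D1:**
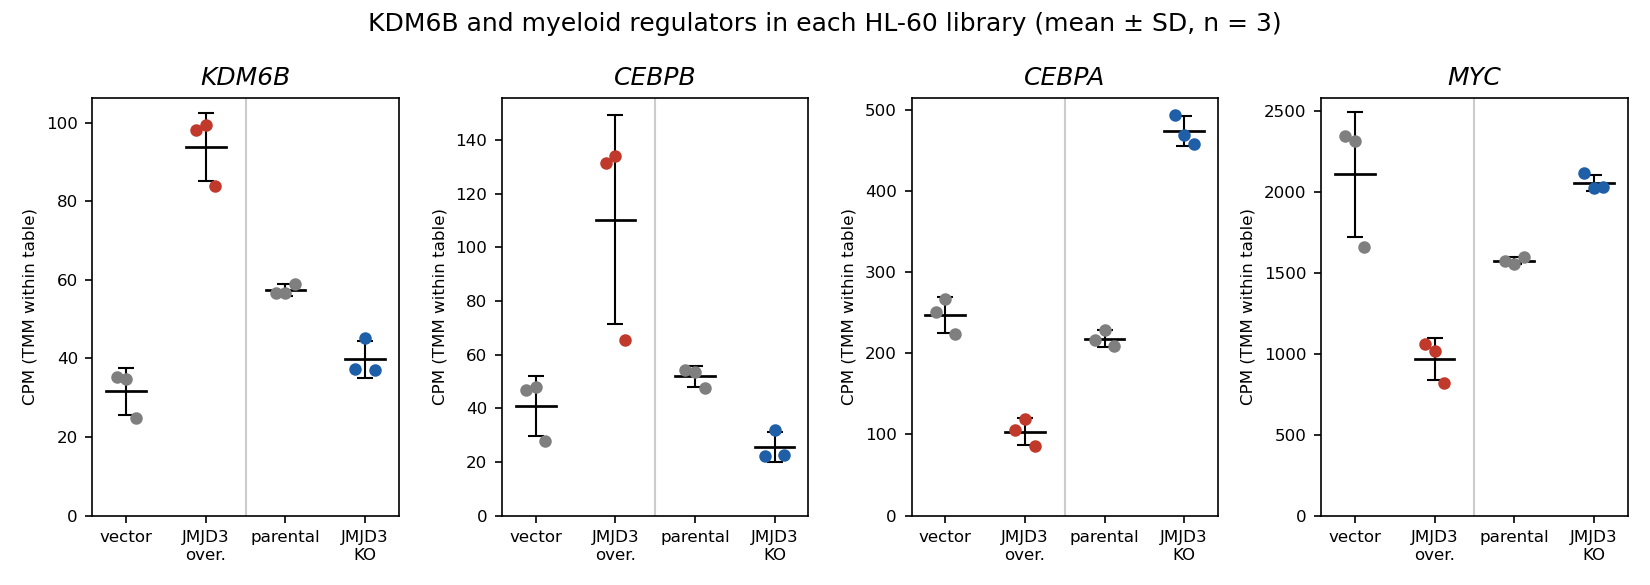
Level of KDM6B, CEBPB, CEBPA and MYC (CPM, normalised within each table) in each library; points are libraries, bars are mean ± SD, n = 3 per group. KDM6B and CEBPB are higher in JMJD3-transduced than in vector cells and lower in knockout than in parental cells, while CEBPA and MYC go the other way. The 2 pairs of groups come from separately scaled tables, so this figure compares levels only within a pair.

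JMJD3 overexpression was accompanied by a broad rise of genes of mature myeloid cells. The calcium-binding protein S100A9 went from 35.6 ± 0.47 to 882.7 ± 18.4 CPM (log2 fold change 4.63 ± 0.067, adjusted p 6.68e-08), and its partner S100A8 rose by 5.43 ± 0.091 on the log2 scale. The integrin subunits ITGAX (CD11c, 6.16 ± 0.10) and ITGAM (CD11b, 3.40 ± 0.096) and the complement receptor CR1 (6.70 ± 0.126) rose as well. At the same time MYC fell from 2107 ± 387 to 965.1 ± 129 CPM (-1.13 ± 0.154, adjusted p 0.000743). The cell cycle inhibitor CDKN1A (p21) went from 0.17 ± 0.18 to 9.33 ± 0.74 CPM (5.56 ± 0.365, adjusted p 2.59e-05). CDKN1A was at 1.73 CPM in the separately scaled parental cells, above the vector control.

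Of 31 listed late neutrophil genes, 21 passed the expression filter. Of these 20 rose and CXCR2 was not called (log2 fold change 0.031). Of 37 listed monocyte and macrophage genes, 18 passed, of which 17 rose and C1QA fell (-2.44 ± 0.273). Among the rises were TLR8 (4.26 ± 0.218), the chemokine receptor CCR1 (1.45 ± 0.081) and the lectin FCN1 (3.37 ± 0.227). The filter keeps a gene that is high enough in a single group. Genes near 0 in the vector control were thus kept only where they were high in overexpressing cells, which favours counts of rises. The list tests drew on these kept members in every setting, so their p-values share this limit. Of 7 genes of the list for the NADPH oxidase, which makes the superoxide of phagocytes (6 subunits and C17orf62, a chaperone of the cytochrome subunits), 6 rose, among them CYBB (0.61 ± 0.20 to 70.8 ± 11.2 CPM) and NCF1 (3.18 ± 0.168), and CYBA was not called. NCF1 has near-identical pseudogene copies, so its count is uncertain. Azurophil granule proteins, made at the promyelocyte stage, went mostly the other way: of 16 measured, 9 fell and 4 rose. PRTN3 (proteinase 3) fell from 839.1 ± 169 to 62.5 ± 9.14 CPM (-3.75 ± 0.186), CTSG fell by 2.08, SERPINB10 fell by 2.22 and MPO fell by 1.05 ± 0.093, while BPI rose by 2.98 ± 0.091, and SRGN, CD63 and NKG7 also rose. In the competitive test over lists (camera, preset correlation), late neutrophil genes had an adjusted p of 1.21e-10 and monocyte genes 1.35e-07. Both calls held with an estimated correlation (0.0399 and 0.028). The NADPH oxidase list had an adjusted p of 0.00142 (adjusted p = 0.197 with an estimated correlation). The azurophil list had 0.0494 (adjusted p = 0.197 with an estimated correlation, and 0.0972 with the replicate number as a block), and its call was lost without overexpression replicate 3 (0.0539). Over all settings its adjusted p ran from 4.77e-05 to 0.197.

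Of 25 NF-kB and inflammatory genes, 21 rose, including the chemokines CCL2 (6.08 ± 0.207) and CXCL8 (14.5 ± 2.21 to 274.4 ± 46.5 CPM), the subunit NFKB2 (2.38 ± 0.087) and TRAF1 (1.39 ± 0.24 to 11.1 ± 0.59 CPM). SOD2, NFKBIA and NFKB1 fell. The list passed with the preset (adjusted p 1.0e-07) and with an estimated correlation (0.0399). Of 28 myeloid transcription factors, 12 rose, 2 fell and 14 were not called. Among the rises were the early-response factors EGR1 (3.95 ± 1.04 to 122.3 ± 10.7 CPM), EGR2 (4.74 ± 0.302), EGR3 (3.44 ± 0.14) and FOS (2.94 ± 0.125). Parental cells, scaled separately, held CXCL8 at 198.4, FOS at 103.9, EGR1 at 28.8, TRAF1 at 4.70 and CCL2 at 3.34 CPM. The vector control was lower in each (FOS 5.52 and CCL2 0.24 CPM), so these rises start from a low control. FOS reached 42.2 CPM on overexpression, below its parental level. CEBPB rose by 1.44 ± 0.31 (adjusted p 0.00641), CEBPA fell by 1.26 ± 0.131 and ATF3 fell by 0.43. In the main fit, which has no pairing term, SPI1 (0.23 ± 0.198) and CEBPE (-0.37 ± 0.18) were not called (adjusted p 0.365 and 0.123). With the replicate block their adjusted p-values were 1.4e-09 and 7.75e-17, with replicates 1 and 2 only 5.53e-12 and 1.27e-17, and with replicates 1 and 2 summed 0.486 and 0.284. Over all settings the highest were 0.746 and 0.305, and CEBPE was also called without vector control replicate 3 (0.0195). The list's adjusted p was 0.00771 (adjusted p = 0.402 with an estimated correlation). CEBPB was at 131.6, 134.0 and 65.3 CPM in the 3 overexpressing libraries and at 46.7, 47.9 and 27.9 CPM in the vector controls. Without a low-count filter its adjusted p was 0.0761, the highest of its settings, which started at 3.81e-33. Of 28 interferon-stimulated genes, 15 rose, such as IFI6 (2.36 ± 0.126) and GBP2 (3.36 ± 0.239), and OAS1, IRF1 and IFIT3 fell (adjusted p 0.0122 for the list, adjusted p = 0.132 with an estimated correlation).

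Genes of growth and sterol synthesis fell. Of 23 cholesterol synthesis genes, 22 fell and TM7SF2 was not called, with LSS at -2.11 ± 0.090, INSIG1 at -1.90 ± 0.076, FDFT1 at -1.63 ± 0.065 and DHCR7 at -1.55 ± 0.066. Of 33 ribosome biogenesis and MYC target genes, 30 fell, 0 rose and 3 were not called, including NCL (-0.86 ± 0.051), NPM1 (-0.90 ± 0.059) and ODC1 (-1.23 ± 0.092). Of 34 G1/S genes, 24 fell, such as TYMS (-1.27 ± 0.061) and MCM7 (-0.94 ± 0.057), and CCNE2, CCND3 and E2F2 rose. These 3 lists passed with the preset (adjusted p 1.78e-13, 3.08e-12 and 1.83e-06) and with an estimated correlation (0.0141, 0.0141 and 0.028). Of 30 G2/M genes, 10 fell, such as BIRC5 (-0.63 ± 0.077), MKI67 and CENPE rose and 18 were not called (adjusted p 0.0116, adjusted p = 0.204 with an estimated correlation). Of 16 cell cycle inhibitors, 9 rose, among them CDKN2B (3.14 ± 0.173) and BTG2 (2.20 ± 0.106), and CDKN2C fell (adjusted p 0.0361, adjusted p = 0.183 with an estimated correlation, and 0.0595 with the replicate block), and the call was lost without vector control replicate 3 (0.0523). Over all settings its adjusted p ran from 1.46e-05 to 0.183. Of 26 genes of the unfolded protein and ATF4 response, 13 fell and 5 rose, with XBP1 at -0.88 ± 0.063 and DDIT4 at 1.47 ± 0.109 (adjusted p 0.0333, adjusted p = 0.17 with an estimated correlation). Of 34 ribosomal protein genes, 7 fell, such as RPL14 (-0.37 ± 0.053), and 27 were not called (adjusted p 0.00184, adjusted p = 0.479 with an estimated correlation). Among all genes tested 3421 of 14322 fell, a similar share.

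Markers of other blood lineages were measured in the same libraries. The filter kept 14 of 24 listed megakaryocyte, eosinophil and mast cell genes and 8 of 22 lymphoid genes. It also kept 4 of 12 MHC class II and 4 of 18 epithelial and fibroblast genes, and the limit given above for rises holds here too. Of 14 megakaryocyte, eosinophil and mast cell genes, 8 rose, including the eosinophil and basophil protein CLC (69.5 ± 4.01 to 940.3 ± 38.9 CPM), histidine decarboxylase HDC (0.22 ± 0.055 to 31.5 ± 1.01 CPM) and IL5RA (2.83 ± 0.159), and PRG2 fell (adjusted p 0.0216, adjusted p = 0.17 with an estimated correlation). Of 8 lymphoid genes, 4 rose, among them CD79B and IL7R, each to 2.57 CPM or less (adjusted p 0.0494, adjusted p = 0.197 with an estimated correlation, and 0.165 with the replicate block). The lymphoid call was also lost without vector control replicate 3 (0.0739) or without overexpression replicate 1 (0.0556), 2 (0.0536) or 3 (0.0539), within a range of 5.77e-06 to 0.197 over all settings. Of 4 measured MHC class II genes, HLA-DPA1, HLA-DMA and CD74 rose and RFX5 fell (-0.25 ± 0.062). The RFX5 call was lost without overexpression replicate 1 (adjusted p 0.0576, range over all settings 1.87e-10 to 0.211). Of 4 epithelial and fibroblast genes, COL1A1, TAGLN and PDGFRB rose, each to 3.95 CPM or less. These last 2 lists were too short to test. Anti-apoptotic genes rose in 6 of 9 members, with BCL2A1 at 4.63 ± 0.204, and BCL2 fell by 1.21 ± 0.094 (adjusted p 0.0216, adjusted p = 0.28 with an estimated correlation). Of 13 mitochondrially encoded genes, 7 rose, such as MT-CO1 (0.87 ± 0.077) (adjusted p 0.00771, adjusted p = 0.469 with an estimated correlation). The share of counts from these genes was 6.75%, 6.62% and 5.82% in the overexpressing libraries and 4.14%, 4.21% and 3.85% in the vector controls.

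The remaining 8 lists did not pass camera with the preset correlation. By fry, which asks only whether a list's genes move on balance one way, 24 of the 26 lists tested passed, and of these 8 only the Polycomb list did not (adjusted p 0.0882). Among the 8, 11 Polycomb and H3K27 enzymes rose and 12 fell of 36, with EZH2 at -0.65 ± 0.063 and KDM6A, the paralog of KDM6B, at 0.41 ± 0.099. With replicates 1 and 2 summed the adjusted p of KDM6A was 0.0809, the highest of its settings, which started at 2.97e-13. HOX genes rose in 5 of 14 members, with HOXA10 at 1 count in the vector controls and 93 in the overexpressing cells (ratio 81.8, 95% counting interval 14.3 to 3264), and HOXD13 fell. Heat shock genes fell in 8 of 14 members, such as HSP90AB1 (-0.82 ± 0.052), and BAG3, HSPA6, HSPA1A and HSPA1B rose, of which HSPA1A and HSPA1B share reads. Hypoxia and glycolysis genes rose in 8 and fell in 9 of 26, stem and progenitor genes in 6 and 7 of 17, pro-apoptotic genes in 8 and 5 of 23, erythroid genes in 2 and 2 of 6, and replication-dependent histone genes in 2 and 0 of 7. Signs differed between median and mean for hypoxia (-0.06 and 0.33), stem and progenitor (-0.08 and 0.60), Polycomb (-0.03 and 0.0005) and heat shock genes (-0.51 and 0.09), and the first 3 medians turned positive under upper-quartile or library-size scaling. Adjusted over the list alone, the counts were the same except for G1/S (3 rose, 25 fell), interferon-stimulated (16 rose, 3 fell), ribosomal protein (0 rose, 3 fell), ribosome biogenesis (0 rose, 31 fell), stem and progenitor (7 rose, 7 fell) and unfolded protein genes (6 rose, 14 fell).

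Among called genes at 5 CPM or more in the higher group that met the naming rule, the largest rises were in FSCN1 (fascin, 2 counts in the vector controls and 2203 in the overexpressing cells, a ratio of 969 with a 95% counting interval of 268 to 8003), CPXM1 (1 and 725 counts, ratio 637.5, 114.1 to 25210), C12orf75 (1 and 567 counts, ratio 498.6, 89.1 to 19730), PADI4, an enzyme of neutrophils (7.59 ± 0.34), HDC, UBB, CYBB and KIAA0226L. UBB shares sequence with other ubiquitin genes and is uncertain. Under the same rule the largest falls were in CBR1 (-5.89 ± 0.282), the surrogate light chain gene IGLL1 (268.2 ± 64.5 to 5.88 ± 1.39 CPM), ZNF37A (-4.22 ± 0.218), UNC5C (17.0 ± 1.95 to 1.07 ± 0.14 CPM), PRTN3, WWC1 (-3.54 ± 0.157) and the near-identical pair CKMT1A and CKMT1B, whose reads cannot be told apart. By edgeR's quasi-likelihood test without a pairing term, with Benjamini-Hochberg adjustment, 7207 of 14322 genes passed an adjusted p of 0.05, 3786 up and 3421 down. Of these, 1688 rose and 327 fell by at least 1 on the log2 scale. With the replicate number as a block, 10489 genes passed, 5215 up and 5274 down. With replicates 1 and 2 of each group summed, 4351 passed, 2662 up and 1689 down. Scaling by library size alone gave 4788 up and 2202 down (68.5% up, against 52.5%) and moved the median of all genes by 0.14, and upper-quartile scaling gave 4389 up and 2660 down. Replicates 1 and 2 alone gave 10016 calls, and of the 9952 tested in both fits 98.0% had the same sign in the third pair of libraries.

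**Figure D2:**
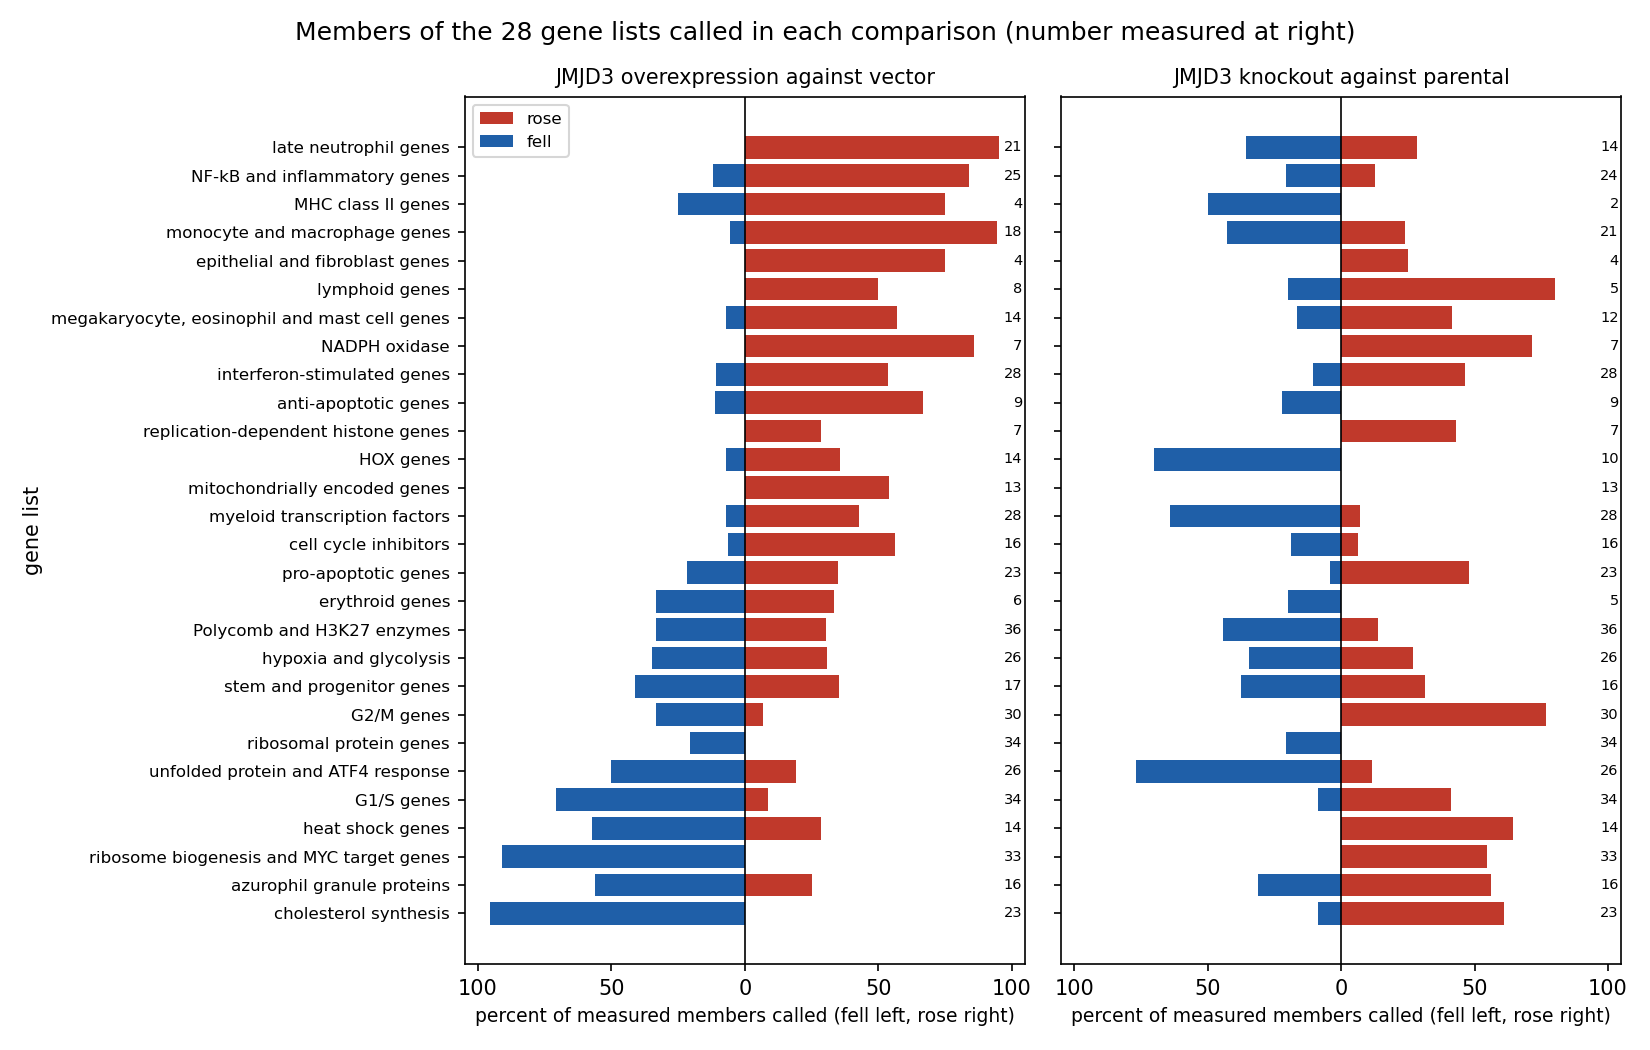
Percent of the measured members of each of the 28 gene lists that rose (right, red) or fell (left, blue) at an adjusted p under 0.05, for JMJD3 overexpression against vector control and for JMJD3 knockout against parental cells; the number measured stands at the right edge. In overexpressing cells 20 of 21 late neutrophil genes rose and 22 of 23 cholesterol synthesis genes fell, and in knockout cells 23 of 30 G2/M genes rose and 20 of 26 unfolded protein and ATF4 response genes fell.

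Between JMJD3 knockout and parental cells 12 gene lists passed camera with the preset correlation, and 0 with an estimated one. In 21 genes every library of one group was at 5 CPM or more and every library of the other under 0.5 CPM. Of ANXA6, CYP51A1, HLTF and FADS1, which all changed strongly, only HLTF was among these 21. ANXA6, a calcium-dependent membrane-binding protein, went from 1.49 ± 0.097 to 140.3 ± 4.60 CPM (6.55 ± 0.073, adjusted p 5.06e-19), and the sterol demethylase CYP51A1 from 2.08 ± 0.38 to 75.5 ± 3.69 CPM. The helicase-like factor HLTF fell from 51.9 ± 2.03 to 0.24 ± 0.087 CPM (-7.73 ± 0.131) and the fatty acid desaturase FADS1 from 105.7 ± 5.09 to 5.69 ± 0.395 CPM. CEBPB fell by 1.01 ± 0.153 (adjusted p 0.00316), CEBPA rose from 218.2 ± 10.2 to 474.2 ± 18.6 CPM (1.12 ± 0.047, adjusted p 1.9e-11) and MYC rose by 0.38 ± 0.042.

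Of 26 genes of the unfolded protein and ATF4 response, 20 fell and 3 rose. The falls included amino acid synthesis genes under ATF4, with ASNS at -1.10 ± 0.049 and PHGDH at -1.11 ± 0.055, and TRIB3 (-1.37 ± 0.062) and VLDLR (-1.76 ± 0.085). The members that rose, CALR (0.38), PDIA4 (0.16) and HSPA5 (0.19), are chaperones of the endoplasmic reticulum. The list had an adjusted p of 7.58e-11 (adjusted p = 0.28 with an estimated correlation). Of 28 myeloid transcription factors, 18 fell, CEBPA and RARA rose and 8 were not called. ATF3 (-1.36 ± 0.095), EGR1 (-0.80 ± 0.074), EGR3 (-2.44 ± 0.256) and SPI1 (-0.35 ± 0.045) were among the falls (adjusted p 0.000438, adjusted p = 0.291 with an estimated correlation). Of 10 HOX genes, 7 fell, including HOXB6 (15.3 ± 1.85 to 3.80 ± 0.39 CPM), HOXA13 (-1.62 ± 0.251) and HOXC10, and 3 were not called (adjusted p 0.000438, adjusted p = 0.28 with an estimated correlation).

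Several lists of division, ribosome production and sterol synthesis passed in the upward direction with the preset correlation, and none did with an estimated one. Of 30 G2/M genes, 23 rose and 0 fell, such as CDC25B (0.70 ± 0.051), HMMR (0.40 ± 0.045) and CDC20 (0.43 ± 0.051), with an adjusted p of 7.35e-09 (adjusted p = 0.291 with an estimated correlation). Of 34 G1/S genes, 14 rose, with CDK6 at 0.94 ± 0.052 and TYMS at 0.45 ± 0.043, and CDT1, CCND2 and E2F2 fell (adjusted p 0.00319, adjusted p = 0.344 with an estimated correlation). Of 33 ribosome biogenesis and MYC target genes, 18 rose and 0 fell, including UTP20 (0.46 ± 0.047) and MRTO4 (0.40 ± 0.050) (adjusted p 1.48e-05, adjusted p = 0.475 with an estimated correlation). Of 23 cholesterol synthesis genes, 14 rose, such as CYP51A1 (5.16 ± 0.093) and NSDHL (0.45 ± 0.064), and TM7SF2 and SREBF2 fell (adjusted p 0.000178, adjusted p = 0.45 with an estimated correlation). Of 14 heat shock genes, 9 rose and 0 fell, such as HSPA8 (0.53 ± 0.059) and HSP90AA1 (0.48 ± 0.058) (adjusted p 0.000205, adjusted p = 0.392 with an estimated correlation). Ribosomal protein genes fell in 7 of 34 members, such as RPL3 (-0.27 ± 0.046), and 2860 of all 14186 genes tested fell, a similar share. By camera the ribosomal protein list had an adjusted p of 0.0447 (adjusted p = 0.747 with an estimated correlation). That call was lost without parental replicate 2 (0.376) or without knockout replicate 2 (0.155) or 3 (0.0689), within a range of 0.000442 to 0.747 over all settings.

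Pro-apoptotic genes rose in 11 of 23 members, among them the death receptor TNFRSF10B (0.49 ± 0.12 to 22.9 ± 1.87 CPM) and CASP1 (2.06 ± 0.129), and BBC3 fell (adjusted p 0.00472, adjusted p = 0.291 with an estimated correlation). Interferon-stimulated genes rose in 13 of 28, such as HERC5 (3.23 ± 0.124) and IFIT3 (1.41 ± 0.128), and OAS3, IFITM1 and STAT2 fell (adjusted p 0.0111, adjusted p = 0.28 with an estimated correlation). Of 36 Polycomb and H3K27 enzymes, 16 fell, such as PHC1 (-0.79 ± 0.077), and PCGF5 (3.02 ± 0.115), KMT2D, PHC2, PHF19 and RBBP7 rose (adjusted p 0.0453, adjusted p = 0.301 with an estimated correlation). The Polycomb call was lost without parental replicate 3 (0.0814) or without knockout replicate 1 (0.0549), 2 (0.0536) or 3 (0.0605), within a range of 0.00331 to 0.301 over all settings. KDM6A was -0.24 ± 0.068 (adjusted p 0.0121) and lost its call without parental replicate 3 (adjusted p 0.0584) or without knockout replicate 1 (0.072), within a range of 0.000574 to 0.0932. EZH2 was not called (-0.06 ± 0.044), and neither was CDKN1A (-0.30 ± 0.216). CEBPE was -0.14 ± 0.045 (adjusted p 0.0217) and lost its call without parental replicate 2 (0.0932) or 3 (0.0957), without knockout replicate 3 (0.119) and with the replicate block (0.0535), within a range of 0.0104 to 0.119.

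The late neutrophil, monocyte and azurophil granule lists each had called members in both directions. Late neutrophil genes rose in 4 (CXCR2, CHI3L1, MMP25 and TREM1) and fell in 5 (ANXA3, S100A9, CSF3R, ITGB2 and FPR2) of 14, and ITGAM was not called (-0.10 ± 0.103). Monocyte and macrophage genes rose in 5 and fell in 9 of 21, with C1QA (3.41 ± 0.72 to 54.2 ± 1.97 CPM) and CSF1R (1.88 ± 0.17) up and CTSL (-4.94 ± 0.163) and LILRB2 (-1.43 ± 0.128) down. Azurophil granule genes rose in 9 and fell in 5 of 16, with PRSS57 at 4.48 ± 0.147 and MPO at -0.28 ± 0.046. The other lists that did not pass camera with the preset correlation were NF-kB and inflammatory genes (3 rose and 5 fell of 24), NADPH oxidase (5 and 0 of 7), cell cycle inhibitors (1 and 3 of 16), hypoxia and glycolysis (7 and 9 of 26), stem and progenitor (5 and 6 of 16), anti-apoptotic (0 and 2 of 9), histone (3 and 0 of 7), mitochondrially encoded (0 and 0 of 13) and erythroid genes (0 and 1 of 5). Of the markers of other cell types, megakaryocyte, eosinophil and mast cell genes rose in 5 and fell in 2 of 12, with ITGA2B at 3.04 ± 0.126, and lymphoid genes rose in 4 and fell in 1 of 5, with CD79A at 1.23 ± 0.091. By fry the monocyte (adjusted p 0.0223), NADPH oxidase (0.0416), histone (0.019), megakaryocyte (0.000214) and lymphoid lists (0.00309) passed. By camera some of these lists passed when a library was left out: megakaryocyte, eosinophil and mast cell genes without parental replicate 1 (0.0335) or 3 (0.0414) or knockout replicate 1 (0.0439), mitochondrially encoded genes without parental replicate 1 (0.00148) or 3 (0.0291), histone genes without parental replicate 3 (0.0418) and NADPH oxidase genes without knockout replicate 3 (0.0415). Epithelial and fibroblast genes (1 and 0 of 4) and MHC class II genes (0 and 1 of 2) were not tested as sets. Median and mean differed in sign for late neutrophil (0.12 and -0.50), azurophil (0.18 and -0.12), hypoxia (0.02 and -0.31), monocyte (-0.27 and 0.006), NF-kB (-0.04 and 0.09) and stem and progenitor genes (-0.10 and 0.18), and the erythroid median of 0.09 stood against a test direction of down. Adjusted over the list alone, the counts were the same except for cholesterol (15 rose, 2 fell), epithelial (1 and 1), heat shock (10 and 0), hypoxia (9 and 9), megakaryocyte (6 and 2), monocyte (5 and 10), Polycomb (6 and 17), pro-apoptotic (12 and 1), ribosomal protein (0 and 5) and ribosome biogenesis genes (20 and 0).

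Among called genes at 5 CPM or more in the higher group that met the naming rule, the largest rises were in ERGIC1 (0 counts in the parental cells and 2190 in the knockout cells, at least 924.5-fold higher against a floor of 3 counts over the group), ZNF273 (7.13 ± 0.29), ZNF331 (7.02 ± 0.336), GAS2L1 (6.94 ± 0.14), CBR1 (6.82 ± 0.18), ZNF37A (6.81 ± 0.124), ZNF322 (6.79 ± 0.269) and ANXA6. Under that rule the largest falls were in HOXC10 (GRCh38 chromosome 12, 53985065 to 53990279), SLC16A14 and ZDHHC21, which had 0 counts in the knockout cells and were at least 315-fold, 236-fold and 220-fold lower, and in ANXA3 (2536 counts in the parental and 2 in the knockout cells, ratio 1001, 95% counting interval 276.9 to 8272), ZNF229 (1014 and 1, ratio 800.7, 143.4 to 31660), SEPT11 (1596 and 2, ratio 630.1, 174.2 to 5208), SEMA4C (-8.58 ± 0.212) and FERMT1 (-8.35 ± 0.204). Floors and counting intervals cover counting error only. ZNF322 is uncertain, since its pseudogene ZNF322P1 rose with it (2 counts in parental and 77 in knockout cells). By the same edgeR test 5357 of 14186 genes passed an adjusted p of 0.05, 2497 up and 2860 down, of which 266 rose and 510 fell by at least 1 on the log2 scale. With limma on log2(FPKM + 1), 2976 passed. Of 26 lists tested by camera, 12 passed with the preset correlation. With an estimated correlation 0 passed, 3 had an unadjusted p under 0.05, and fry called 16.

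**Figure D3:**
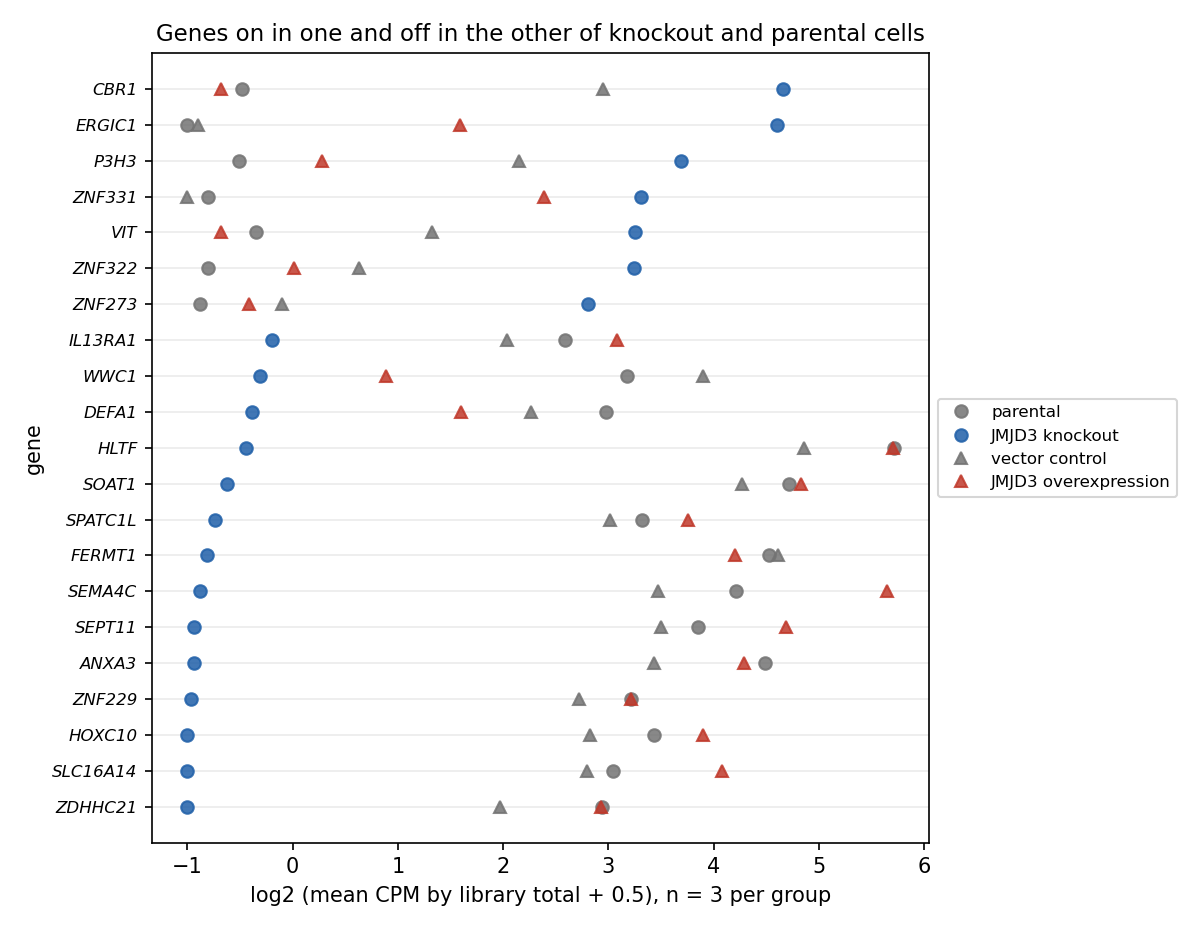
Mean level (log2 of CPM by library total plus 0.5, n = 3 per group) of the 21 genes at 5 TMM-scaled CPM or more in every library of one group and under 0.5 in every library of the other, between parental and knockout cells (circles), with the vector control and JMJD3-transduced cells beside them (triangles). Of these genes 7 were on and 14 were off in the knockout cells, and HOXC10, SLC16A14 and ZDHHC21 were at 0; the triangles come from a separately scaled table.

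Genes that changed in both comparisons went mostly in opposite directions. Among 13721 genes tested in both, 3176 were called in both, and 2328 of these (73.3%) went opposite ways. Genes that rose on overexpression and fell on knockout numbered 1198, where independent calls would give 703.1 (odds ratio 2.88, 95% interval 2.63 to 3.15, adjusted p 1.16e-118, two-sided Fisher's exact test). Genes that fell on overexpression and rose on knockout numbered 1130 against 610.4 (odds ratio 3.36, 3.06 to 3.69, adjusted p 1.29e-142). The 435 that rose in both and the 413 that fell in both were fewer than the 606.7 and 707.4 of independent calls (odds ratios 0.605 and 0.446, adjusted p 8.04e-20 and 1.76e-50). Genes are not independent replicates, so these p-values describe the gene sets. Across genes the log2 fold changes had a Pearson correlation of -0.21 and a Spearman correlation of -0.28. The comparisons share no control libraries.

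CEBPB and EGR3 rose on overexpression and fell on knockout, and MYC, TYMS and INSIG1 fell on overexpression and rose on knockout. Of the genes that the naming rule took from those called in both, CBR1, ZNF37A, MSRB3, VIT and ZNF566 fell on overexpression and rose on knockout, and FAM129B did the reverse (4.01 ± 0.12 and -4.03 ± 0.361). The 2 control groups, scaled separately, already differed in these genes. CBR1 was at 7.60 CPM in the vector control and 0.217 CPM in parental cells, ZNF37A at 6.97 and 0.540, and MSRB3 at 2.06 and 0.0793. VIT was at 2.10 and 0.286, ZNF566 at 0.547 and 0.018, and FAM129B at 0.873 and 2.02 CPM. Each fall thus started from a higher control than the rise of the same gene. ZNF331, ERGIC1 and COL4A2 rose in both, and WWC1 fell in both (-3.54 ± 0.157 and -4.74 ± 0.212). ASNS and PHGDH fell in both comparisons, by 0.99 and 0.98 on overexpression and by 1.10 and 1.11 on knockout. MPO also fell in both. With log2 fold changes of at least 1 in both, 274 genes went opposite ways and 100 the same way. With overexpression replicates 1 and 2 summed, 1477 went opposite ways.

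**Figure D4:**
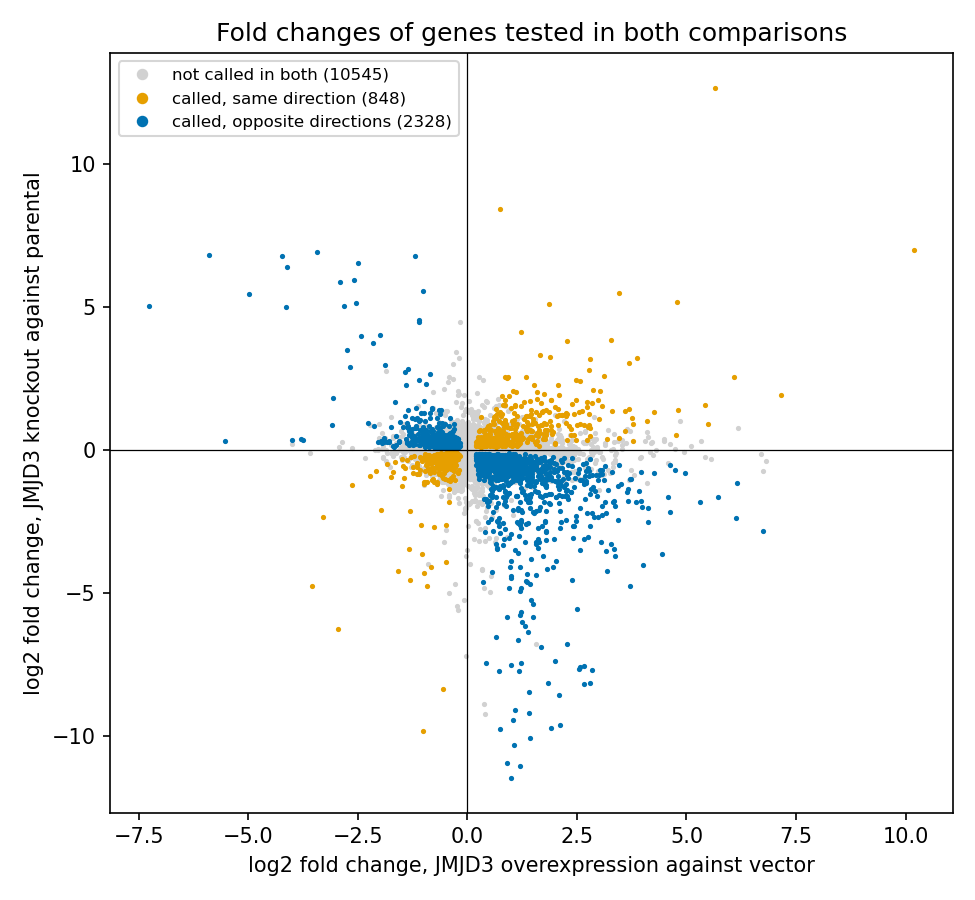
Log2 fold change of each of the 13721 genes tested in both comparisons, JMJD3 overexpression against vector control on the x axis and JMJD3 knockout against parental cells on the y axis. The 2328 genes called in opposite directions (blue) outnumber the 848 called in the same direction (orange), and grey points were not called in both.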

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

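The FPKM, batch-term, undivided-column, summed-replicate and replicates 1 and 2 settings were chosen after the data were seen, the others before. The tables hold counts per gene, so the planned pseudocount and transcript alternatives were not run. Counts of genes, in all and per direction, stayed within 1.5 times of the reported value except as follows. A required log2 change of at least 1 left 2015 genes on overexpression, 776 on knockout and 274 opposite in both, since small changes are removed. Replicates 1 and 2 summed, which leaves 2 libraries per group, gave 4351 genes, 1689 of them down, and 1477 opposite genes. Genes that fell on overexpression numbered 2202 with library size only, 5274 with the replicate block and 5311 with the batch term. On log2(FPKM + 1) 2463 genes rose on overexpression and 2976 passed on knockout (1609 up, 1367 down), and KDM6B was -0.449 there (adjusted p 0.155, from 2.95e-17 over its settings); the cause was not tested. With an estimated correlation 6 overexpression and 0 knockout lists passed (3 knockout lists at an unadjusted p under 0.05, and 16 by fry). Leaving out each library gave 5848 to 7626 overexpression calls, 4335 to 5313 knockout calls, 1922 to 2465 opposite calls, and KDM6B changes of 1.43 to 1.66 and -0.62 to -0.48. With the replicate block 10489 genes passed on overexpression and 15 of its lists. In the knockout, where same-numbered libraries did not deviate together, the block gave 4597 genes and 14 lists, and the block in both fits gave 2686 opposite genes. Beyond the calls given in the report, the block ended those of RPS27A (overexpression, 0.0903) and NCF1 (knockout, 0.0582), added those of LUM (0.0331) and HIST1H2BK (0.00266) on overexpression and of the megakaryocyte (0.0494) and mitochondrially encoded lists (0.0196) on knockout, and changed no other call among the named genes and lists. Of all genes called, 34 (overexpression) and 61 (knockout) had the other sign in the authors' deposited table and 23 and 53 on log2(FPKM + 1), and 0 in each other setting. The named genes and lists that turned direction had not passed as reported, and the cause was not tested. In the turned direction, up, the overexpression lists of hypoxia (adjusted p 0.000908) and stem and progenitor genes (0.0172) passed by fry. HIST2H2BE was -0.77 in the authors' deposited table and -0.023 with replicates 1 and 2 only. For lists the direction of the test turned while the median log2 change was as follows. On overexpression, hypoxia was -0.05707 without a filter, -0.05281 with summed replicates, -0.05692 by fry and -0.05203 to -0.005551 over left-out libraries, and stem and progenitor was -0.07661 by fry. On knockout by fry, erythroid was 0.09362, NF-kB -0.03554 and stem and progenitor -0.09788. Over left-out knockout or parental libraries, erythroid ran from 0.06071 to 0.1507, hypoxia from 0.01593 to 0.05624, late neutrophil from -0.01885 to 0.1455, NF-kB from -0.03568 to 0.03295 and stem and progenitor from -0.1783 to -0.06683. Of single-gene results over the alternatives, 4850 kept direction and side of the threshold, 46 lost and 19 gained a call. Of single-list results 509 kept both, 48 lost and 24 gained a call. Depth limits genes near 0, given as counts.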

Other observations

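The tests of a batch, of clone differences, of all-or-none genes, of library-size scaling, of zinc finger genes and of genes far lower in knockout cells were chosen only after the result was seen, and so were the genes named next. Some single genes of lipid metabolism lay outside the fixed lists, and no set of them was tested. FADS2 and FADS1, which desaturate polyunsaturated fatty acids, fell on overexpression (FADS2 from 41.8 ± 2.52 to 6.73 ± 0.789 CPM, FADS1 from 54.0 ± 3.38 to 17.9 ± 0.957 CPM) and on knockout (FADS2 from 74.6 ± 4.14 to 32.1 ± 3.02 CPM, FADS1 by -4.21 ± 0.069). The stearoyl desaturase SCD fell on overexpression from 816.0 ± 61.5 to 212.8 ± 20.1 CPM and was not called on knockout (0.03 ± 0.046). FASN, the fatty acid synthase, fell on overexpression (-1.06 ± 0.087) and rose on knockout (0.41 ± 0.041). SOAT1, which esterifies cholesterol, went from 25.7 ± 0.494 to 0.148 ± 0.146 CPM on knockout. Values in CPM are means ± SD (n = 3 per group), and the others are log2 fold changes ± SE.

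On overexpression 22 genes went from under 0.5 CPM in every vector control library to 5 CPM or more in every overexpressing library, by TMM-scaled CPM, and 1 went the other way. Levels of these genes are given here as mean CPM by library total. Besides genes named in the report they include the carboxylesterase CES1 (0.371 to 16.5 CPM), the SRC-family kinase FGR (0.307 to 15.1 CPM), the B cell lectin CD22 (0.155 to 6.05 CPM), the neutrophil granule protein CRISP3 (0.0917 to 6.25 CPM), coagulation factor F5 (0.3 to 6.70 CPM) and the adhesion molecule ICAM1 (0.278 to 11.6 CPM). CES1 is uncertain, since its pseudogene CES1P1 rose too (2 counts in the vector control and 128 in the overexpressing cells).

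Between parental and knockout cells 21 genes were all-or-none in this sense. Reads shared with near-identical genes are argued against for most of them, since 98.4% of their expected counts in the expressing group were whole within 0.02. The 88.9% for other genes at 5 CPM or more in every library of a group is not a matched standard, since it has no upper limit on level. DEFA1, which has near-identical copies, is uncertain. So is ZNF322, since its pseudogene ZNF322P1 rose too (2 counts in parental and 77 in knockout cells). Loss of a chromosome segment is argued against too: 0% of the 14 lost genes had a lost nearest expressed neighbour (exact 95% upper limit 23.2%). Differences between lines or clones cannot be told apart from the knockout, since the sources used here do not give the clones behind the libraries. The vector control lay nearer to the knockout than to the parental cells for 2 of the 21 genes (9.52%), CBR1 (7.22 CPM in vector control, 0.218 in parental and 24.7 in knockout cells) and P3H3 (3.95, 0.204 and 12.4 CPM), in separately scaled tables. An effect of JMJD3 loss stays open.

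The third replicates of both overexpression groups stood apart from the others. A difference in total counts alone is argued against, since their deviations from the group means still correlated at 0.523 after thinning each library to the smallest total, against 0.553 before; other differences, such as in genes detected, were not matched. A separate batch fits the values: factors computed with the third replicates apart matched the deposited scaling within 1.34%, against 18.9% otherwise. Their deviation also followed GC content across genes (Spearman -0.644, length 0.0939, with a value for 99.4% of genes), so a library batch with another GC profile may be the source. Both groups share it, and no biological explanation was tested.

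Genes called in both comparisons went mostly opposite ways, and trends or scaling as the whole cause are argued against. After trends with GC content, length and level were removed, the Spearman correlation of fold changes was -0.261, against -0.278 before. With library size as the only scaling 74.3% (2238 genes) went opposite ways. The 27 all-or-none genes among them were too few to move the share, which was 73.4% (2310 genes) without them, and decide nothing. Of 100 pairs of splits of the libraries, 1, the real one, gave as many opposite genes (2328, highest other 0), but no other split called any gene (edgeR, up to 577 and 621 at an unadjusted p under 0.05), so its count of 0 was fixed and says nothing of chance. A candidate explanation is that part of these genes follow the JMJD3 level in both directions, which stays a hypothesis since clone and control differences are open. KDM6B was at 31.6, 57.4 and 39.8 CPM in vector control, parental and knockout cells, scaled separately, and MYC at 2107, 1574 and 2054. TYMS was at 442.2, 292.1 and 397.7 and CEBPB at 40.8, 51.9 and 25.6. In these genes vector control and knockout lay on the same side of parental cells, but not in INSIG1 (122.8, 137.4 and 176.8). Whether control differences add to the opposite calls was not tested.

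A hypothesis from the same tables is that genes far lower in the knockout cells follow the JMJD3 level. Of 69 genes called in both and lower in knockout by at least 4 on the log2 scale (fold change -4 or less), 60 (87%) rose on overexpression, against 73.8% (1138 of 1542) of those with milder falls (odds ratio 2.37, 95% interval 1.15 to 5.47, p = 0.0157, two-sided Fisher's exact test). This comparison group replaced a first one, all other genes called in both, which restated the opposite directions. The result may also be read as chance levels of the same genes in different HL-60 lines. Zinc finger genes made up 4 of the 21 all-or-none genes, against 254 of 9450 in the background (odds ratio 8.63, 2.10 to 26.7, p = 0.00213, two-sided Fisher's exact test), and genes are not independent replicates. ZNF322, named above as uncertain, is among the 4. Among the all-or-none genes on overexpression 0 of 22 coding genes were zinc finger genes, against 261 of 9703 (95% interval of the odds ratio up to 6.63). The intervals of the 2 comparisons overlap and their difference was not tested, so whether they differ is open.

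With 3 libraries against 3 there are 10 splits of each comparison, too few for a share under 0.05. In each case 1 split, the real one, gave as many. On overexpression 7207 genes and 18 lists passed in the real split, and at most 0 genes (edgeR, up to 577 at an unadjusted p under 0.05) and 12 lists in the others. The other splits that part all 3 same-numbered pairs each exchange 1 pair of libraries between the groups, and gave 0 genes (11, 8 and 22 at an unadjusted p under 0.05) and 11, 10 and 8 lists. On knockout 5357 genes and 12 lists passed, and at most 0 genes (edgeR, up to 621 unadjusted) and 10 lists in the others.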
